A study of Arabidopsis thaliana with 16 samples.

How the data were processed

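Gene expression was measured in 14-day-old Arabidopsis seedlings (Columbia background) on 16 Affymetrix ATH1 arrays, 2 for each of 8 groups. The groups cross 2 genotypes, wild type and a line overexpressing the rice gene OsGRX8, with 4 conditions of 3 h each: water, 100 µM indole-3-acetic acid (IAA, the main natural auxin), 200 mM NaCl, and 25 µM methyl viologen (MV, a herbicide that takes electrons from photosystem I and passes them to oxygen, giving superoxide). Plants grew in 16 h light and 8 h dark, and 500 ng of total RNA went into each labelling, per the labels' protocols. The design text calls the 2 arrays of a group biological replicates. OsGRX8 encodes a CC-type glutaredoxin, a small thiol-disulfide oxidoreductase of a class specific to land plants. The level of the rice transgene itself was not analysed here.

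The deposited values are log2 probe set summaries, 1 column per array, and RMA (background correction, quantile normalization and median polish) is named per the submitters' processing notes, without a version. The software and the probe set definitions are not given in the sources used here. The log base was read from the values: bacterial hybridization transcripts added at 1.5, 5, 25 and 100 pM had slopes between 0.839 and 1.06 against log2 of their nominal concentration, and no array was centred per gene. Array medians lay between 2.94 and 3.20. Of 22810 probe sets, 64 were Affymetrix controls and 22746 were tested. Probe sets were named from the platform annotation: 13513 had 1 gene, 503 had several and were not named, and 8730 were unnamed here. Of the 13513, 13436 matched a gene identifier in the RefSeq gene table, and no symbol needed an update. Of the 13356 genes named, 11799 carry a locus code only, so that many familiar stress and auxin genes have no named probe set here.

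One linear model of the 8 group means was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend), with 8 residual and 4.52 prior degrees of freedom. The 14 comparisons were each treatment against water in each line, the lines against each other in each condition and over the mean of the 4 conditions, and the difference between the lines' responses (interaction). Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Errors given with log2 fold changes are standard errors (SE) from this fit, with 2 arrays per group. The number of arrays limits the precision: the median half-width of a 95% confidence interval was 0.45 on the log2 scale (1.37-fold) for 2 groups, 0.23 for the mean of 4 conditions and 0.64 for an interaction.

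The tests, the gene lists and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 8 largest increases and the 8 largest decreases past the threshold among probe sets of exactly 1 gene whose arrays did not overlap between the groups. Where none passed, it took the 3 smallest p-values in each direction. It added up to 4 members of each fixed list and any glutaredoxin, and the text names a subset, which skips some higher-ranked genes. For a gene with several probe sets, the one with the highest mean stood for it. Of 25 fixed lists, 6 had at least 5 measured genes and were tested with camera (preset inter-gene correlation of 0.01), adjusted over 84 tests. Lists were matched by symbol, and 2 matches name other genes than intended: FDH in the leaf epidermis list is the formate dehydrogenase locus AT5G14780, and CCR2 in the clock list is the cinnamoyl-CoA reductase locus AT1G80820. Responses of the lines were also compared by the correlation across probe sets and by the overlap of calls, since the lines share no array. Their calls do share the spread of each probe set, pooled over all groups.

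The pipeline was tested on simulated data with 200 changed probe sets among 22746 and the observed spread of each group. In the water comparison of the lines it recovered 0% of changes of 0.5, 41.8% of changes of 1 and 97% of changes of 2 (log2), and called 0 unchanged probe sets. For the mean of 4 conditions, 50.7% of changes of 0.5 and 94% of changes of 1 were recovered, with 6 unchanged probe sets called. For the MV interaction, 5.97% of changes of 1 and 81.8% of changes of 2 were recovered. For IAA in the wild type, whose arrays spread more than those of the other groups, 62.7% of changes of 1 were recovered and 54 unchanged probe sets were called. Alternatives were a repeated quantile normalization, median centring, a filter that kept 13647 brighter probe sets, an intensity trend, array weights, fits on the compared arrays only, the replicate number as a block, removal of probe sets with cross-hybridization suffixes (21685 left), a 2-fold threshold, and each array left out in turn. For lists, an estimated correlation, fry and the mean of all probe sets of a gene were added.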

Results

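The study asked how seedlings overexpressing a rice CC-type glutaredoxin differ in gene expression from the wild type, without treatment and after auxin, salt or methyl viologen. Each of the 8 groups held 2 arrays. Replicate arrays correlated at 0.966 to 0.994 over 22746 probe sets, and no 2 arrays were identical. The wild type IAA arrays were the least alike, with a replicate SD of 0.42 on the log2 scale against 0.18 in the overexpression line in water. The first principal component held 47.8% of the variance and set the 4 NaCl arrays apart from the other 12. On IAA replicate 2, the 3′ probe set of the actin control exceeded the 5′ one by 6.1 in the wild type and by 4.43 in the overexpression line (log2), against 1.36 to 1.85 on the water arrays.

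After 3 h of IAA, measured early auxin genes rose in both lines. They were among 47 probe sets past the test in the wild type and 49 in the overexpression line, most of them outside the auxin list. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose by 4.36 ± 0.38 on the log2 scale in the wild type (20.5-fold, adjusted p = 0.000421, limma) and by 4.83 ± 0.38 in the overexpression line (28.4-fold). IAA29, a member of the Aux/IAA family of auxin signalling repressors, rose by 4.19 ± 0.42 and 4.92 ± 0.42. LBD29, a transcription factor of lateral root formation, rose by 2.98 ± 0.48 and 3.18 ± 0.48. In water LBD29 (1.5 and 1.43), IAA29 (1.82 and 1.58), GH3.1 (1.26 and 1.21) and LBD16 (1.62 to 1.79 over the arrays of both lines) had signals near that of the absent trp control (0.83 to 0.889 on the water arrays), so their log2 changes may be understated. All 8 measured genes of the auxin primary response list rose in the wild type and 7 rose in the overexpression line, and adjusted over the list alone 8 rose in each. The eighth there was GH3.1, at 1.26 ± 0.24. The list passed camera in both lines, also with an estimated correlation (adjusted p = 0.00267 and 0.000421). WES1 (GH3.5) rose by 2.26 and 2.68, IAA30 by 1.96 and 2.17, LBD16 by 1.64 and 1.88, and the homeobox gene HAT2 by 1.64 and 2.37. Outside the list, AT4G17350 rose by 2.59 and 2.24, AT3G42800 by 1.95 and 1.62, AT1G64405 by 2.88 in the wild type, and AT5G62280 by 2.17 in the overexpression line.

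In all, 47 probe sets passed in the wild type (44 higher, 3 lower) and 49 in the overexpression line (47 higher, 2 lower). AT3G52480 fell in both lines (-1.25 ± 0.22 and -1.22 ± 0.22), and AT3G05220 fell in the wild type (-0.85 ± 0.15). None of the 5 glutaredoxins passed in either line, and GRX480 stood at 0.30 ± 0.39 and 0.65 ± 0.39. The 7 nuclear light-harvesting and photosynthesis genes had a median of -0.33 in the wild type with none past the test. That list was lower than other genes by camera (adjusted p = 0.0152), but with an estimated correlation the adjusted p = 0.684. The 9 cell wall expansion genes were higher by camera in the overexpression line (adjusted p = 0.0129), with none past the test singly and adjusted p = 0.407 with an estimated correlation. For thr, a bacterial transcript added as a control, the 3′ probe set exceeded the 5′ one by 3.01 to 3.66 on the 4 IAA arrays. It did so by at most 2.84 on the others, so a difference in processing may go with IAA. These arrays include IAA replicate 2 of both lines, with the weak 5′ signal given above. Without both of these arrays, an alternative chosen after seeing the data, 32 probe sets passed in the wild type and 57 in the overexpression line, and LBD29 (2.14), IAA30 (1.63), AT3G52480 (-0.97) and AT3G05220 (-0.71) no longer passed in the wild type. In the overexpression line AT5G62280 (2.27, adjusted p = 0.0514) and AT3G52480 (-1.08, adjusted p = 0.156) no longer passed without these arrays.

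The wild type count rests on the spread pooled over all groups: it was 0, with no named gene past the test, when only the wild type water and IAA arrays were fitted, and simulated data with the spread of these groups gave 54 calls among unchanged probe sets. It was 31 with quantile normalization, 17 with array weights, 14 and 12 without water replicate 1 or 2, 27 without IAA replicate 2 and 3372 (43.1% of them higher) without IAA replicate 1. LBD29 no longer passed in the wild type with quantile normalization or array weights (adjusted p = 0.0567 and 0.144), without water replicate 1 or 2 (0.222 and 0.237) or without IAA replicate 2 (0.137). Other calls lost there were AT1G64405 with quantile normalization (adjusted p = 0.0559), IAA30, AT3G52480 and AT3G05220 with array weights (0.0815, 0.298 and 0.312), AT3G52480 and AT3G05220 with the intensity trend (0.065 and 0.0669) and AT3G05220 on brighter probe sets (0.0786). The 3 left-out arrays that ended the LBD29 call also ended the calls of AT4G17350 (adjusted p at most 0.114), AT3G52480 (0.501) and AT3G05220 (0.495), the 2 water arrays that of AT1G64405 (0.257), and water or IAA replicate 2 that of IAA30 (0.179). In the overexpression line the count was 77 with array weights, 18 and 15 without water replicate 1 or 2, and 30 and 19 without IAA replicate 1 or 2. AT3G52480 no longer passed there with the intensity trend (adjusted p = 0.0677) or on the compared arrays (0.139). Without any 1 of these 4 water and IAA arrays, LBD29 (adjusted p from 0.0849 to 0.188), AT5G62280 (0.0559 to 0.188) and AT3G52480 (0.0963 to 0.733) no longer passed in the overexpression line. AT4G17350 no longer passed there on the compared arrays (adjusted p = 0.122) or without water replicate 1 or 2 or IAA replicate 2 (0.188, 0.164 and 0.134), nor did IAA30 without water or IAA replicate 2 (0.0655 and 0.0507).

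**Figure D1:**
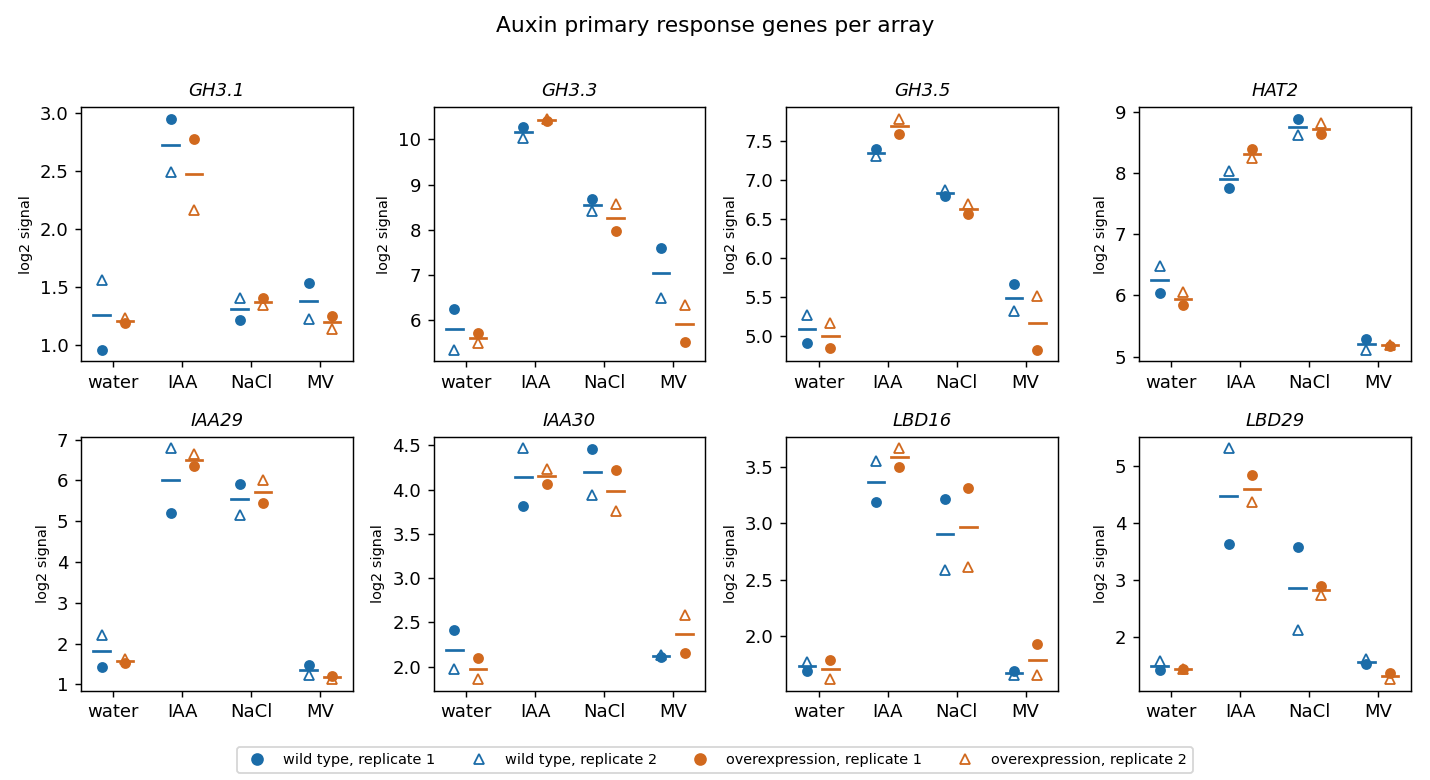
Signal (log2) of the 8 auxin primary response genes on each of the 16 arrays, by condition and line, with the vertical axis set per gene. Symbols are single arrays and bars are means of 2 arrays, and the mean rise of GH3.3 under IAA is 4.36 in the wild type and 4.83 in the overexpression line.

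Salt changed more genes than either other treatment, with increases of up to 49.2-fold among named genes in the wild type. AT1G73480, which encodes an alpha/beta hydrolase, rose by 5.62 ± 0.50 in the wild type and 5.73 ± 0.50 in the overexpression line. ORA47, an AP2/ERF transcription factor of the jasmonate response, rose by 5.28 ± 0.25 and 5.86 ± 0.25 (58.1-fold, adjusted p = 7.41e-08, limma). The largest decreases were those of AT5G48430, at -4.94 ± 0.32 and -4.96 ± 0.32, and of AT2G47550, a pectin methylesterase gene, at -4.93 ± 0.36 and -4.71 ± 0.36. XTH18, which encodes a xyloglucan-modifying enzyme of the cell wall, fell in both lines (-4.06 ± 0.23 and -4.02 ± 0.23).

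Of the 8 auxin genes, 6 also rose under NaCl in each line, and 7 did when adjusted over the list alone. IAA29 rose by 3.72 and 4.14, GH3.3 by 2.75 and 2.66, HAT2 by 2.50 and 2.78, and IAA30 by 2.01 in both. GH3.1 stood at 0.05 ± 0.24 and 0.17 ± 0.24. The list passed camera in both lines, and with an estimated correlation the adjusted p = 0.0469 in the wild type and 0.048 in the overexpression line. Both measured type-A response regulators, which are induced by cytokinin and repress its signalling, rose: ARR15 by 2.35 and 2.4 and RR16 (ARR16) by 2.22 and 2.33. Among 9 cell wall expansion genes, 2 rose and 3 fell in each line (adjusted over the list alone, 2 and 3 in the wild type and 3 and 3 in the overexpression line). The expansin genes EXPB3 (2.57 and 2.16) and EXPB1 (1.05 and 0.83) rose, while XTH19 (-2.74 and -2.28) and XTH16 (-1.68 and -1.47) fell. Camera did not separate that list from other genes (adjusted p = 0.557 and 0.536).

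Among 5 glutaredoxins, GRX480, a CC-type member also called ROXY19, rose by 2.46 ± 0.39 and 2.84 ± 0.39 under NaCl, and GRXC1 fell (-0.94 ± 0.19 and -0.88 ± 0.19). Adjusted over the list alone, 2 rose and 1 fell in the wild type, and 2 rose and 2 fell in the overexpression line. Of 13 glutathione S-transferases, GSTU16 rose in both lines (1.19 and 1.09) and GSTU27 fell by 1.54 in the overexpression line, with the same counts adjusted over the list alone. SAG101, which acts in plant immunity, fell (-1.78 and -1.42), and so did PDF1.2b, a defensin gene (-2.33 and -2.84), and CCR2, the cinnamoyl-CoA reductase gene AT1G80820 (-2.04 and -3.12). WRKY53 rose by 1.53 in the wild type and stood at 0.53 ± 0.38 in the overexpression line (limma, adjusted p = 0.441). In the overexpression line AT5G48570 fell by 2.81 and the glucosinolate gene UGT74B1 by 0.61. In the wild type these 2 genes stood at -1.59 ± 0.56 and -0.35 ± 0.19, not past the test (limma, adjusted p = 0.0861 and 0.286). Adjusted over its list alone, AT5G48570 passed there too (limma, adjusted p = 0.0298). None of the 4 antioxidant enzyme, 3 flavonoid or 3 sulfur response genes passed under any treatment in either line, nor did EIN3, AMS, OLEO3 or PYK10, each the only measured member of its list. With adjustment over the list alone, the sulfur response genes APS3, SIR and BGLU28 rose under MV in the overexpression line (0.71, 0.57 and 0.61, limma adjusted p at most 0.043). None of the 3 passed under MV in the wild type by that measure, while APS3 fell there under IAA (-0.88, limma adjusted p = 0.0105). Of the 4 measured cold- and salt-responsive genes, COR15B rose under NaCl in the overexpression line (1.39 ± 0.41) and stood at 0.81 ± 0.41 in the wild type. EXPA7, a root hair expansin gene, fell (-0.66 and -0.61), to signals near background (1.33 and 1.51). Further increases included AT5G03230 (4.30 and 3.94), AT1G78070 (3.73 and 3.59) and AT1G48100 (3.63 and 3.93), a polygalacturonase gene. Further decreases included AT2G32190 (-4.35 and -4.44), AT2G44380 (-4.26 and -4.38), AT5G19890 (-4.11 and -4.36), AT5G55050 (-4.11 and -4.63) and Prx37, a peroxidase gene (-3.84 and -4.22).

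Under NaCl, 3211 probe sets passed in the wild type (1731 higher, 1480 lower) and 3569 in the overexpression line (1806 higher, 1763 lower). UGT74B1 no longer passed on the compared arrays only (adjusted p = 0.0654), nor did EXPA7 in the wild type with quantile normalization (adjusted p = 0.0656), nor UGT74B1 with the intensity trend (adjusted p = 0.101). With median centring the higher share was 49.4% and 49.2%, in place of 53.9% and 50.6%, and in the overexpression line it was 48.6% on brighter probe sets and 47.7% without NaCl replicate 1. With a threshold of 2-fold the counts were 1911 and 2118. The wild type count was 5095 with array weights, 1754 and 1982 without water replicate 1 or 2, and 2054 and 1870 without NaCl replicate 1 or 2. The overexpression count was 2115 and 1984 without water replicate 1 or 2 and 2368 without NaCl replicate 2. Among wild type calls, EXPA7 was lost without water replicate 1 or 2 or NaCl replicate 2 (adjusted p at most 0.281), WRKY53 without water replicate 1 or either NaCl array (0.136), GRXC1 and PDF1.2b without water replicate 1 or NaCl replicate 2 (0.0583 and 0.0517), and EXPB1 without NaCl replicate 2 (0.0523). Among overexpression calls, EXPA7 was lost without any 1 of the 4 arrays (adjusted p at most 0.237), XTH16 and UGT74B1 without either water array or NaCl replicate 2 (0.0992 and 0.29), and COR15B without either water array or NaCl replicate 1 (0.264). GRXC1 and GSTU27 were lost there without water or NaCl replicate 2 (adjusted p at most 0.0645 and 0.0633), and AT5G48570 without water replicate 1 or NaCl replicate 2 (0.0594).

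Under methyl viologen the glycosyltransferase gene UGT73B5 and the glutaredoxin gene GRX480 were among the genes that rose most in both lines. UGT73B5 rose by 4.05 ± 0.32 in the wild type (16.6-fold, adjusted p = 3.85e-05, limma) and 3.4 ± 0.32 in the overexpression line. GRX480 rose by 3.72 ± 0.39 and 3.73 ± 0.39, and none of the other 4 measured glutaredoxins passed in either line. AT1G53540 (3.99 and 3.83) and AT2G29500 (3.65 and 3.1), which encode cytosolic small heat shock proteins, rose, and AT1G54050, of the same family, rose by 3.12 and 3.22. AT1G22810, an ERF-type transcription factor gene, rose by 3.83 and 3.82.

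Of 4 oxidative stress signalling genes, 2 rose in each line under MV: the zinc finger gene STZ (ZAT10), by 1.97 ± 0.34 and 1.83 ± 0.34, and WRKY6, by 1.96 ± 0.27 and 1.45 ± 0.27. Adjusted over the list alone, all 4 rose in the wild type and 2 in the overexpression line. HSA32, a heat acclimation gene, rose by 1.0 ± 0.21 in the overexpression line and stood at 0.68 ± 0.21 in the wild type. No member of the glutathione S-transferase list passed, with GSTU25 at 1.48 ± 0.53 and 1.52 ± 0.53. In the wild type COR15A (-1.34 ± 0.32), the iron-deficiency regulator PYE (-1.18 ± 0.27), HAT2 (-1.06 ± 0.18) and the stomatal lineage regulator SPCH (-0.89 ± 0.20) fell, while XTH18 rose by 1.07 ± 0.23. COR15A (-0.86 ± 0.32), PYE (-0.99 ± 0.27) and SPCH (-0.315 ± 0.195) also stood lower in the overexpression line, not past the test (limma, adjusted p = 0.336, 0.119 and 0.727). HAT2 stood there at 5.17 and 5.19 under MV against 5.84 and 6.05 in water. The 5 leaf epidermis and guard cell genes were lower by camera in the wild type (adjusted p = 0.0389), with 1 past the test and 4 adjusted over the list alone. Of these 4, MUTE stood at 0.95 under MV against 1.38 in water, and the absent trp control at 0.957 and 0.988 on these MV arrays, so MUTE was not above background there. The fifth gene, TRY, stood at 0.18 ± 0.19. With an estimated correlation the adjusted p = 0.54, and 1 of the 5 is the formate dehydrogenase gene FDH. AT5G62280 fell in both lines (-2.46 ± 0.31 and -1.92 ± 0.31), as did AT3G62550 (-2.16 and -1.45) and AT5G57760 (-2.16 and -1.86). In the overexpression line, 5 of the 8 largest decreases were chloroplast-encoded genes: rps18 (-1.98 ± 0.40), ndhA (-1.88 ± 0.37), rbcL (-1.78 ± 0.33), psbM (-1.54 ± 0.26) and petA (-1.49 ± 0.24).

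Under MV, 984 probe sets passed in the wild type (582 higher, 402 lower) and 331 in the overexpression line (275 higher, 56 lower). Fitted on the compared arrays only, SPCH, COR15A and rps18 no longer passed (adjusted p = 0.0545, 0.0699 and 0.0711), and neither did HSA32 with quantile normalization, median centring or the intensity trend (adjusted p = 0.0805, 0.0783 and 0.0658). With median centring the higher share in the wild type was 73.1% in place of 59.1%. Without the 4 IAA arrays, an alternative chosen after seeing the data, the counts were 1489 and 570, and array weights gave 958 in the overexpression line. The wild type count was 514 and 300 without water replicate 1 or 2 and 347 without MV replicate 1, and the overexpression count 131 and 86 without water replicate 1 or 2 and 136 without MV replicate 2. In the overexpression line, leaving out any 1 of the 4 compared arrays ended the calls of ndhA, rbcL, HSA32 and WRKY6 (adjusted p at most 0.267, 0.175, 0.304 and 0.229), and either water array or MV replicate 2 those of psbM, petA, AT5G57760 and STZ (0.142, 0.098, 0.342 and 0.212). Either water array or MV replicate 1 ended those of rps18 and AT3G62550 there (adjusted p at most 0.233 and 0.151), and water replicate 2 or MV replicate 1 that of AT5G62280 (0.116). In the wild type, any 1 of the 4 arrays ended the call of PYE (adjusted p at most 0.252), either water array or MV replicate 1 those of COR15A and XTH18 (0.31 and 0.183), water replicate 2 or MV replicate 1 those of SPCH, STZ and AT5G57760 (0.221, 0.0572 and 0.0752), and water replicate 2 that of HAT2 (0.0889).

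Responses were alike between the lines, which share no array. Across probe sets, the responses of the lines correlated at 0.909 for NaCl, 0.772 for MV and 0.558 for IAA, against 0.0548 to 0.136 for 6 pairs of different treatments. These are correlations across genes, which are not independent replicates. Of the calls, 2504 were shared in direction for NaCl, 294 for MV and 31 for IAA, and 0 had opposite directions. Independent lists would share 137 higher and 115 lower for NaCl, 7.04 and 0.99 for MV, and 0.0909 and 0.000264 for IAA. These numbers are too low as a reference, since the calls of both lines rest on the same spread per probe set, pooled over all groups. Of the 984 probe sets called for MV in the wild type, 970 had the same sign in the overexpression line. The IAA correlation was 0.273 without both IAA replicate 2 arrays and 0.24 without that of the overexpression line. With 1 array left out, the shared IAA calls numbered from 12 (without wild type water replicate 2) to 63 (without wild type IAA replicate 1), and the shared MV calls as few as 83 (without overexpression water replicate 2).

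**Figure D2:**
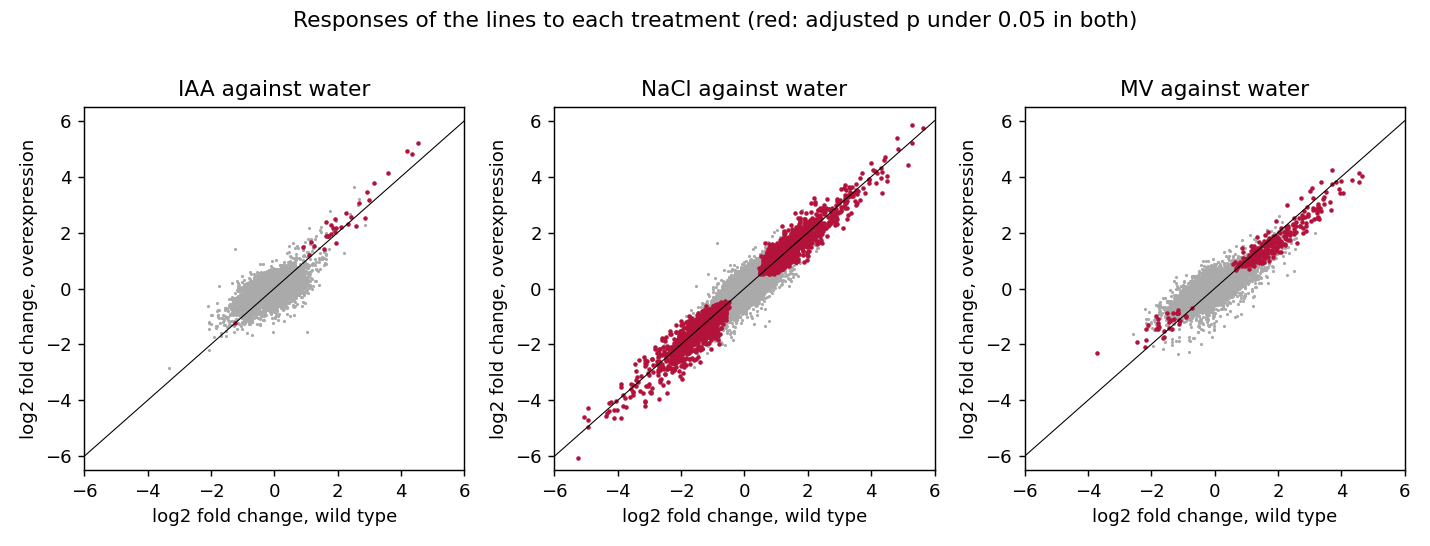
Log2 fold change against water in the wild type (horizontal) and in the overexpression line (vertical) for IAA, NaCl and MV, with 1 point per probe set and a line at equal response. Red points passed an adjusted p of 0.05 in both lines: 31 for IAA, 2504 for NaCl and 294 for MV.

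No gene passed the test between the overexpression line and the wild type in any condition. In water, the named genes with the smallest p-values included AT1G68580, at -0.56 ± 0.15, AT2G25420, at 0.51 ± 0.15, and AT2G20142, at 0.83 ± 0.27, all with an adjusted p of 1. Of the glutaredoxins and the other fixed lists, no member passed in any of these comparisons. With adjustment over the list alone (limma), some members of lists with 2 measured genes did. EXPA7 was higher in the overexpression line under MV (0.82 ± 0.19, adjusted p = 0.00165) and over the 4 conditions (0.39 ± 0.09, 0.00253). So was UGT74B1 (0.63 ± 0.19, 0.0111, and 0.24 ± 0.09, 0.0464). SAG101 was lower under IAA (-0.51 ± 0.19, 0.0398) and MV (-0.57 ± 0.19, 0.0221). Adjusted over all probe sets (limma), these were 0.367 and 0.57 for EXPA7, 0.637 and 0.791 for UGT74B1, and 0.631 and 0.762 for SAG101. Adjustment over the list alone does not count the other lists or comparisons. Under MV EXPA7 stood near background, at 1.46 in the wild type and 2.28 in the overexpression line. The absent trp control stood at 0.868 to 0.988 on these arrays. In limma, 0 probe sets passed in water, with 255 at an unadjusted p under 0.05 (1.12% of 22746, below the 5% that chance gives, under a spread pooled over all groups). A difference in 1 gene below about 1.37-fold lay inside the median 95% interval. Larger differences could also be missed after adjustment: in the simulated water comparison, 0% of log2 changes of 0.5 and 41.8% of changes of 1 were recovered.

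Under IAA, 0 probe sets passed between the lines in limma, with 1666 at an unadjusted p under 0.05. AT3G05220 stood at 0.91 ± 0.15 and AT1G68585 at -1.11 ± 0.18, neither past the test (adjusted p = 0.324). The light-harvesting list was higher by camera in the overexpression line (adjusted p = 0.0378, median 0.26), with adjusted p = 0.723 with an estimated correlation. Without wild type IAA replicate 1, which leaves the array with the weakest 5′ signal alone in its group, 1922 probe sets passed, among them AT3G05220 and AT1G68585 (adjusted p = 0.00652 and 0.00951). Under NaCl, 0 passed, with 1018 at an unadjusted p under 0.05, and AT3G49810 stood at -1.25 ± 0.25 and AT5G23680 at 0.79 ± 0.15.

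Under MV the 3 named genes with the smallest p-values among those lower in the overexpression line were chloroplast-encoded, and none passed. rpoC2, a subunit of the plastid RNA polymerase, stood at -1.94 ± 0.27, petA at -1.57 ± 0.24 and rps19 at -1.15 ± 0.18 in the overexpression line against the wild type (adjusted p = 0.119 each, limma). Among genes on the other side, AT5G58570 stood at 1.33 ± 0.19 and AT5G17820 at 1.91 ± 0.30. In all, 0 probe sets passed and 1212 had an unadjusted p under 0.05, while median centring gave 9 (0 higher), of which 7 were chloroplast-encoded and which included rpoC2, petA and rps19 (adjusted p = 0.0175, 0.0175 and 0.0455). The intensity trend and the replicate number as a block gave 1 each, rpoC2 (adjusted p = 0.0431 and 0.00392). The count was 7 without wild type MV replicate 2, with rpoC2 among them (adjusted p = 0.0361), and 2 without overexpression MV replicate 2, and median centring moved the median of all probe sets to -0.13.

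Averaged over the 4 conditions, the named genes with the smallest p-values included the chloroplast genes petG (-1.07 ± 0.21) and ndhG (-1.0 ± 0.21) and the nuclear genes AT5G65120 (-0.46 ± 0.09), AT5G19850 (0.38 ± 0.07), AT1G11850 (0.51 ± 0.10) and AT5G17820 (0.78 ± 0.15), each with an adjusted p of 0.57. In limma, 0 probe sets passed for the mean of 4 conditions, and 1331 had an unadjusted p under 0.05. Without wild type IAA replicate 1 the count was 1.

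The responses of single genes did not differ detectably between the lines after adjustment over all probe sets. Adjusted over its list alone, the MV interaction of EXPA7 passed (0.69 ± 0.26, limma adjusted p = 0.0448), for a gene near background. The named genes with the smallest p-values were AT3G05220 for IAA (1.04 ± 0.21), AT5G23680 for NaCl (1.01 ± 0.21) and AT3G51280 for MV (0.96 ± 0.20), each with an adjusted p of 1. For IAA the auxin list stood higher in the overexpression line than in the wild type by camera (median 0.33, adjusted p = 0.0378) and so did the light-harvesting list (median 0.31, adjusted p = 0.0303), but with an estimated correlation the adjusted p = 0.605 and 0.723. In limma, 0 probe sets passed for each of the 3 interactions, with 647, 491 and 501 at an unadjusted p under 0.05 for IAA, NaCl and MV. The median 95% interval of an interaction reached 1.55-fold on each side, and without wild type IAA replicate 1 the IAA interaction gave 133 probe sets, among them AT3G05220 (adjusted p = 0.0465).

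**Figure D3:**
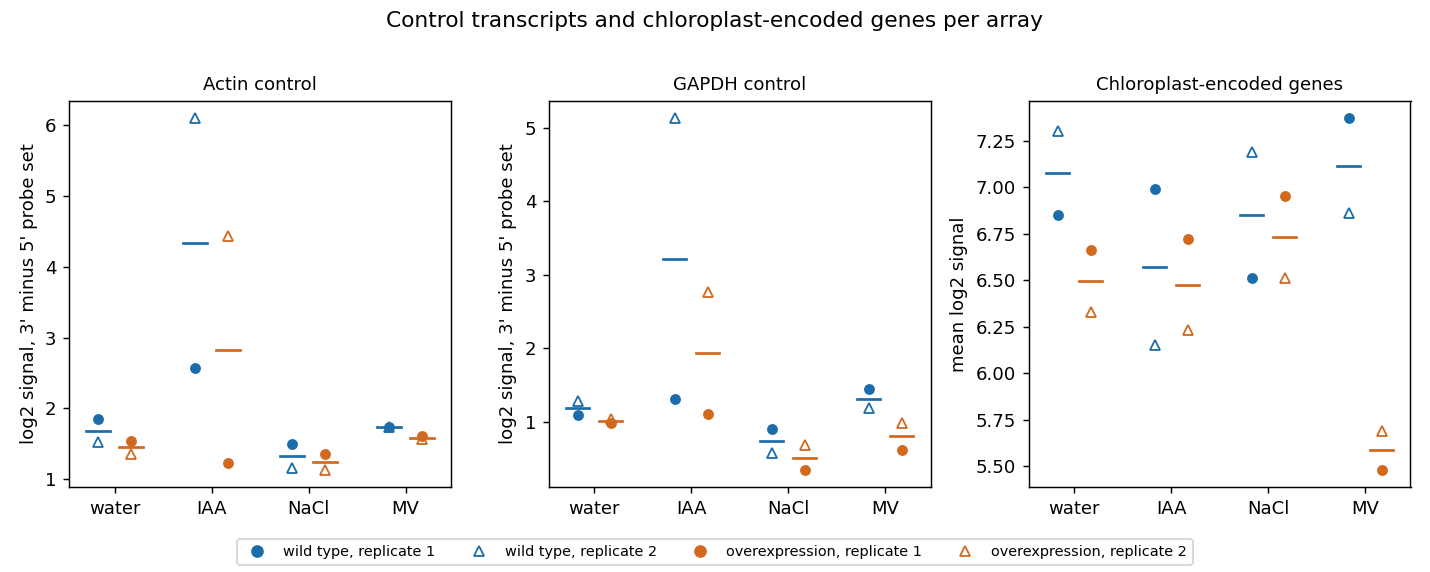
Log2 signal of the 3′ minus the 5′ probe set for the actin and GAPDH controls, and mean log2 signal of 69 chloroplast-encoded genes, on each of the 16 arrays (symbols, with bars for means of 2 arrays). IAA replicate 2 lies highest for actin, at 6.1 and 4.43, and the overexpression MV arrays lie lowest for the chloroplast genes, at 5.48 and 5.69.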

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

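Apart from the camera tests of the auxin and light-harvesting lists, the tests in this part were chosen after the results were seen. On 3 of the 4 IAA arrays, control transcripts had weaker 5′ signal than on water arrays, while overexpression IAA replicate 1 had 1.23 for actin, 1.11 for GAPDH and 1.85 for ubiquitin, none of the 3 above the water arrays. The log2 signal of the 3′ minus the 5′ probe set exceeded the highest water array by more than the range of the water arrays in 9 cases. For actin it was 2.57 and 6.1 on wild type IAA replicates 1 and 2 and 4.43 on overexpression IAA replicate 2. For GAPDH it was 5.13 on wild type replicate 2 and 2.76 on overexpression replicate 2. For ubiquitin it was 2.38 and 3.06 on the wild type replicates and 2.67 on overexpression replicate 2. For dap, a bacterial transcript added as a control, it was 4.04 on overexpression replicate 2.

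IAA treatment as the whole cause of the weak 5′ signal would raise actin on every IAA array. On overexpression IAA replicate 1 actin stood at 1.23, below the highest water array. That is a single array, and the cases above all lay on IAA arrays, so the question stays open for the plant transcripts. The added transcript thr, which the plant does not make, stood higher on the 4 IAA arrays than on the 12 others. A difference in processing may thus go with the IAA arrays, and comparisons of IAA with water may carry it. For the other added transcript, dap, only the replicate 2 arrays stood above the rest. Breakdown of the plant RNA before labelling would leave added transcripts within the range of other arrays, but dap stood at 2.87 and 4.04 on the replicate 2 arrays, against at most 2.21 elsewhere. A short labelling product would raise both added transcripts above every other array, but thr, another added transcript, stood at 3.01 and 3.31 on these arrays and at 3.66 and 3.2 on the replicate 1 IAA arrays, against at most 2.84 on the 12 others. Because the added transcripts differ, breakdown and short product cannot be told apart, and no biological explanation other than IAA treatment was tested.

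The MV response of chloroplast-encoded transcripts, a set chosen after seeing the data, did not pass between the lines after adjustment (camera with an estimated correlation, p = 0.0122, adjusted p = 0.0569, fry adjusted p = 0.19), nor did that of mitochondrial ones (camera with an estimated correlation, p = 0.0082, adjusted p = 0.0574, fry adjusted p = 0.0864). Under MV 69 of 69 chloroplast genes were lower in the overexpression line, with a median of -1.52 (adjusted p = 0.0144 with an estimated correlation), and of -1.66 with median centring. Less green tissue as the main cause is argued against, since it would lower the nuclear light-harvesting list too. The mean difference of its 7 genes was 0.06, with a 95% interval from -0.47. That lies above -0.77, the bound set from the chloroplast mean of -1.53. A smaller loss of green tissue cannot be excluded, since the interval reaches -0.47. Whether MV changed these nuclear genes by itself was not part of this test. Weaker priming of organelle RNA cannot be told apart from a difference between the lines, because the 15 mitochondrial genes were lower under MV too. They had a mean of -0.54, with 14 lower (camera with an estimated correlation, adjusted p = 0.03, fry adjusted p = 0.0125). The 25S rRNA probe set was not lower (8.71 and 8.82 against 8.5 and 8.16), but it is a poor measure, at 2.53 and 9.01 on the wild type water arrays. Over the 4 conditions the chloroplast mean was -0.58 (exact permutation test within conditions, two-sided, p = 0.0401 over 1296 relabellings), made up of -0.58 in water, -0.10 under IAA, -0.12 under NaCl and -1.53 under MV (68, 36, 43 and 69 of 69 genes lower), a scope set after this p was seen because the MV arrays alone allow no p under 0.05, and an effect of the transgene stays an untested hypothesis.

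The MV response was smaller in the overexpression line over 1701 MV-responsive probe sets, with a mean of 1.12 in the wild type and 0.89 in the overexpression line, and 77.7% of them moved less there. Compressed signal at hybridization or later is argued against, since the spike-in slopes of the MV arrays had a ratio of 0.956 (SE 0.0399) and the responses one of 0.79. The slope ratio cannot show compression at steps before the hybridization transcripts were added, so that stays open. It replaced a first test on the SD of each array after its result was seen. Chance among the arrays stays open, with an unadjusted fry p of 0.0526 for the interaction and adjusted p = 0.158 over 3 treatments, though the unadjusted fry p was 0.0477 without the chloroplast probe sets and 0.0292 for the lines under MV. The array scores were 1.18 and 1.03 in the wild type against 0.797 and 1.01, and a weaker response through the transgene is an untested hypothesis.

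By camera, the IAA responses of the auxin and light-harvesting lists differed between the lines, with adjusted p = 0.0378 and 0.0303, but with an estimated correlation the adjusted p = 0.605 and 0.723. For the mean of 4 conditions, where limma called 0 probe sets and 1331 had an unadjusted p under 0.05, 100 of 100 splits of the line labels within conditions gave at least as many, as any split must, so this count decides nothing. The highest other split called 52 and 34 other splits called at least 1, and whether a structure among the arrays besides the line lies behind these was not tested.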

How the results depend on the processing

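The fits without IAA arrays were chosen after seeing the data. No correlation between the lines and no named gene in the treatment comparisons reversed its direction, and the cause of the changes below was not tested, except that a 2-fold threshold removes calls by construction. For named genes and passing gene lists in the treatment comparisons, counted together, 1716 of 1905 values under an alternative kept their side of the threshold, 189 no longer passed and 0 reversed. The share of NaCl calls that were higher went below 50% with median centring (49.4% and 49.2%), and the chloroplast median between the lines under IAA went from -0.03 to 0.02 with median centring, 0.40 without wild type IAA replicate 1 and 0.15 without overexpression IAA replicate 2. Under NaCl it went from -0.09 to 0.20 without wild type NaCl replicate 2 and 0.12 without overexpression NaCl replicate 2. With an array left out, the lone array of its group is assumed to vary like the others. IAA calls in the wild type (47) became 31 with quantile normalization, 17 with array weights, 0 on the compared arrays and 12 to 3372 with 1 array left out. IAA calls in the overexpression line (49) became 77 with array weights and 15 to 30 with 1 array left out. NaCl calls became 5095 with array weights in the wild type, 1911 and 2118 at 2-fold, and 1754 to 2054 and 1984 to 2565 with 1 array left out. MV calls became 1489 and 570 without the 4 IAA arrays or without both IAA replicate 2 arrays, 958 with array weights in the overexpression line, and 300 to 837 and 86 to 335 with 1 array left out. Between the lines, where 0 passed, MV gave 9 with median centring and 1 with the intensity trend. With 1 array left out the counts between the lines were 0 to 7 under MV, 0 to 1922 under IAA, 0 to 1 for the mean of 4 conditions and 0 to 133 for the IAA interaction. The 10 gene list calls became 4 with an estimated correlation, 4 with fry, 6 with quantile normalization, 4 on brighter probe sets, 2 without the 4 IAA arrays and 5 to 16 with 1 array left out. Correlations between the lines were 0.273 for IAA without both IAA replicate 2 arrays, and 0.932 for NaCl and 0.828 for MV on brighter probe sets. With 1 array left out they were 0.24 to 0.633 for IAA, 0.871 to 0.9 for NaCl and 0.662 to 0.746 for MV. Shared calls were 17 for IAA and 659 for MV with array weights, 1559 for NaCl at 2-fold, 478 for MV without the IAA arrays, and 12 to 63, 1539 to 1930 and 83 to 288 with 1 array left out. By replicate number, 9 of 28 pairs of groups had deviations correlated above 0.1 (range -0.108 to 0.363). This shows no pairing of the arrays over all groups, but it cannot exclude a partial one. The IAA groups correlated at 0.363, and their replicate 2 arrays both had the weak 5′ signal. With the replicate number as a block, MV between the lines gave 1 call in place of 0. MV then lowered 1 chloroplast gene in the wild type in place of 0. The other totals of calls moved by less than 1.5 times, though AT3G52480 in both lines and AT3G05220 in the wild type no longer passed for IAA.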

Other observations

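All tests in this part were chosen after the results were seen. Genes raised by IAA were often also raised by NaCl in the other line, which shares no array. Of 47 probe sets raised by IAA in the overexpression line, 24 were raised by NaCl in the wild type, against 3.58 for independent lists (Fisher's exact test, p = 3.55e-15), and 3 were lowered. Of 44 raised by IAA in the wild type, 19 were raised by NaCl in the overexpression line, against 3.49 (Fisher's exact test, p = 2.32e-10), and 2 were lowered. For MV, 0 of the 47 were raised in the wild type against 1.2 for independent lists (Fisher's exact test, p = 0.635) and 1 of the 44 in the overexpression line against 0.532 (Fisher's exact test, p = 0.415). MV lowered 5 of the 47 in the wild type, against 0.831 for independent lists, and 0 of the 44 in the overexpression line, against 0.108, which was not tested. Genes are not independent of each other, and all comparisons share the spread of a probe set pooled over all groups. Probe sets of low spread thus pass more easily in both lists. The numbers for independent lists are therefore too low, and these p-values are too small.

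Under MV in the wild type, the 15 mitochondrial genes had a median of 0.41, with 2 higher and 0 lower by limma (for the set, camera adjusted p = 0.0574 with an estimated correlation and 6.67e-05 with the preset one, fry adjusted p = 0.0125). The 69 chloroplast genes had a median of -0.2 there, with 2 higher and 0 lower, and 12 of them fell and 0 rose in the overexpression line. These 12 became 29 with array weights, 24 on the compared arrays, 25 without the 4 IAA arrays or without both IAA replicate 2 arrays, and 2 to 10 with 1 array left out. The wild type 0 became 2 with array weights, 4 on the compared arrays, 3 without the 4 IAA arrays or without both IAA replicate 2 arrays and 1 with the replicate number as a block, and the median there was 0.08 without MV replicate 2. Among 29 families of genes that share a symbol stem, 32 of 406 tests passed camera with the preset correlation and 0 with an estimated one.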
